A study of Homo sapiens with 6 samples.

How the data were processed

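RNA-seq counts were deposited by the authors as a single table of 61852 Ensembl gene IDs for 6 libraries of Ishikawa cells. Per the labels, 3 libraries are controls and 3 come from cells overexpressing ETV6. The protocols given with the samples describe TRIzol extraction, an input of 1.3 µg RNA, selection of polyadenylated RNA and library preparation with the VAHTS Universal V8 kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to hg38 with HISAT2 and counted per gene with featureCounts. The versions of these tools, the gene annotation, the strand setting of the counting and the handling of reads that fit several genes are not given in the sources used here.

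The deposited counts were used as given. Of the gene IDs, 61803 matched a symbol and 58298 matched GENCODE release 29, from which hg38 coordinates and gene types were taken, and 31340 had no count in any library. The 46 copies of genes in the pseudoautosomal region of chromosome Y were left out of naming. Total counts lay between 21606064 and 25285796 per library, and a count of 0 was read as not detectable at this depth, with a floor of 3 counts, or 0.119 to 0.139 CPM. Such floors cover counting error only. The 13 mitochondrially encoded genes were at 0 in all libraries, so a gene at 0 throughout may also have been removed before or during counting, to which the floor does not apply. Between 21536 and 22737 genes were detected per library, and the 10 most abundant genes held 17.2 to 18.5% of the counts. Counts of libraries of the same group were compared by a chi-square test, and their differences exceeded sampling noise by 12.1-fold to 41.3-fold, so no library was treated as a duplicate.

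Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (min.count 10, min.total.count 15), which left 13802 genes. Libraries were scaled with TMM factors, which lay between 0.95 and 1.079. The ETV6 and control groups were compared with edgeR's robust quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the threshold. The standard error of a log2 fold change was taken as its absolute value over the square root of the F statistic. The biological coefficient of variation was 0.125. CPM values are mean ± SD with n = 3, and principal components were computed on log2 CPM with a prior count of 2.

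The gene lists, 36 with 859 symbols, were fixed before the data were examined, as were the comparison, the filter, the thresholds, the rule for naming genes and the alternatives apart from those stated as added. Each list with at least 3 tested members was tested with camera of limma 3.58.1, at a preset correlation of 0.01 and again with an estimated correlation, and with fry. With an estimated correlation camera also uses the residual degrees of freedom of the libraries, which are few, rather than those of the genes. Camera compares a list with the other genes, whereas fry asks whether the members of a list move on balance in 1 direction. Their p-values were adjusted over the lists. The list counts were also adjusted over the list alone, that is, with the Benjamini-Hochberg method over the members of that list.

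The rule named ETV6, FBXW7, every tested SLC2A gene, HK2, PFKFB3, PKM and LDHA. It added the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, and the up to 4 changed members of each list with the smallest adjusted p. OAS1, IFITM1, BST2, ISG15, ATF4, MPC1 and SUCLG1, and every other gene outside this rule, were chosen after their values were seen. The effect of leaving out libraries was computed for the genes that the rule names and for the lists. A fit that leaves out a library has fewer samples, so a call can be lost while the fold change stays alike.

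The alternatives were RLE, total-count and upper quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the quasi-likelihood fit without the robust option, glmTreat against a log2 fold change of 0.26, thresholds of 0.01 on the adjusted p and of 1 on the log2 fold change, a replicate block and leaving out each library in turn. Offsets for GC content and length, and 5 further gene lists, were added after the data were seen. The p-values of the 5 further lists were adjusted over those 5. The rules by which hypoxia, unfolded protein response, blood-cell and further-list values count for or against an explanation were made stricter after the values were seen. By the earlier rules, oxygen shortage, blood cells and a joint rise of mucin and squamous genes would have counted as argued against. A lower unfolded protein response and a joint fall of the early secretory pathway would have counted as met. Overlap of exons between genes was computed from GENCODE release 29 on both strands. The methods were tested on simulated data with the depth and spread of these libraries, in which 42 of 80 genes changed 1.5-fold, 69 of 80 changed 2-fold and 40 of 40 changed 4-fold were called. Of 13602 unchanged genes, 13 were called, among 164 calls in all. The changed genes were drawn from those with a mean above 1 CPM, so the shares called do not cover genes of lower expression. A simulated list that changed was called, and 0 of 20 unchanged lists were called by camera. The simulated genes varied independently of each other, and the members of the changed list rose at least 1.5-fold. The simulation therefore does not show how camera performs on lists of correlated genes or on smaller shifts. The 13 mitochondrially encoded genes, all at 0 counts, were not tested.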

Results

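Gene expression was measured in Ishikawa cells, an established human endometrial adenocarcinoma line, by sequencing polyadenylated RNA. The 6 libraries fell into 2 groups of 3: a control group and a group made to overexpress ETV6. The control samples are labelled as blank controls. The growth protocol, the same for all 6 samples, describes lentiviral infection with either a vector written EV or an ETV6 construct, so it is not settled which vector, if any, the controls carried. If they carried none, infection and vector differ between the groups along with ETV6, for every gene compared. The labels call the samples of a group biological replicates, and whether they came from separate infections or from a shared pool of infected cells is not given in the sources used here. The p-values therefore measure the spread between these samples. The total counts of control replicates 1, 2 and 3 were 22417347, 21606064 and 24124079. Those of ETV6 replicates 1, 2 and 3 were 24883068, 22190600 and 25285796. A single count was worth between 0.0396 and 0.0463 CPM. After the filter on low counts, 13802 genes were tested. Expression values are CPM scaled with TMM factors and given as mean ± SD with n = 3 per group. Changes are log2 fold changes of the ETV6 group over the control group, from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

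The comparison asked which transcripts differed between ETV6-overexpressing and control cells, and the series title places the interest in FBXW7, glucose metabolism and the GLUT glucose transporters. ETV6 itself, an ETS-family transcriptional repressor, stood at 2.96, 3.01 and 3.85 CPM in control replicates 1, 2 and 3. It stood at 7.49, 6.40 and 6.98 CPM in ETV6 replicates 1, 2 and 3. The mean rose from 3.27 ± 0.50 to 6.96 ± 0.55 CPM, a 2.12-fold difference (SE 0.18 on the log2 scale, adjusted p = 9.43e-04). ETV6 (ENSG00000139083.11) is a protein-coding gene on the plus strand of chromosome 12, from 11649854 to 11895402 in hg38. How much of the ETV6 transcript the construct carries is not given in the sources used here, so the share of its reads that the gene count captures is unknown. FBXW7, the substrate receptor of a ubiquitin ligase that marks several oncoproteins for degradation, stood at 12.6 ± 0.77 CPM in the control group and 10.5 ± 1.42 CPM in the ETV6 group. That difference did not pass the test (log2 fold change -0.26, adjusted p = 0.341).

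SLC2A1, which encodes the glucose transporter GLUT1, rose 2.54-fold in the ETV6 group, from 124 ± 26.6 to 315 ± 33.0 CPM. LDHA, the lactate dehydrogenase subunit that turns pyruvate into lactate, rose 1.49-fold, from 1420 ± 60.5 to 2115 ± 61.9 CPM. PFKP, the platelet-type phosphofructokinase, rose 1.32-fold, from 29.4 ± 2.54 to 38.7 ± 1.15 CPM. The log2 fold changes in the edgeR test were 1.35 for SLC2A1 (SE 0.14, adjusted p = 4.95e-06), 0.58 for LDHA (SE 0.12, adjusted p = 0.00839) and 0.40 for PFKP (SE 0.10, adjusted p = 0.0392). SLC2A1 (ENSG00000117394.24) lies on the minus strand of chromosome 1 from 42925375 to 42959176, and 2.7% of its annotated exonic bases also belong to other genes. LDHA (ENSG00000134333.14) lies on the plus strand of chromosome 11 from 18394388 to 18408425, with no annotated exonic overlap. The call on LDHA was lost without control replicate 1 (adjusted p = 0.0792), without ETV6 replicate 2 (adjusted p = 0.0705) and with glmTreat (adjusted p = 0.122). The log2 fold change of LDHA lay between 0.540 and 0.602 in all 17 alternatives run on it. The call on PFKP was lost without any library other than ETV6 replicate 3, with adjusted p from 0.0875 to 0.164, and also with total-count scaling (adjusted p = 0.099), no filter on low counts (0.0539), limma-voom, the fit without the robust option, the replicate block (0.0649) and glmTreat (0.524).

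Of the 14 glucose transporter genes, 8 were tested, of which 1 rose, none fell and 7 did not pass. The other tested members were SLC2A4, SLC2A6, SLC2A8, SLC2A9, SLC2A11, SLC2A12 and SLC2A13, with log2 fold changes from -1.04 for SLC2A4, the insulin-responsive transporter GLUT4, to 0.55 for SLC2A11. In the control and ETV6 groups SLC2A4 stood at 0.88 and 0.43 CPM, SLC2A9 at 0.69 and 0.46 and SLC2A11 at 0.39 and 0.58. Their standard errors were 0.49 to 0.51 on the log2 scale, so a change in them could be missed. SLC2A8, the next most abundant member, stood at 10.99 ± 1.82 CPM in controls and 11.5 ± 2.20 CPM with ETV6. SLC2A3, which encodes the neuronal-type transporter GLUT3, and its close copy SLC2A14 had 0 counts in every library, as did SLC2A2. A count of 0 allows a level of up to 0.119 to 0.139 CPM per library if the gene was counted, which is not known for genes at 0 throughout. Reads shared between SLC2A3 and SLC2A14 could be lost in counting. Adjusted over the list alone, the same number of transporters rose. As a set the list did not differ from other genes (camera adjusted p = 0.867), and its signs were mixed, with a median of -0.15, a mean of -0.01 (0.25 with no filter on low counts, 0.19 with a filter of at least 1 CPM in 3 libraries, 0.06 without control replicate 2), a camera direction of down and a fry direction of up. Of the 24 tested glycolysis genes, 2 rose, none fell and 22 did not pass, and adjusted over the list alone 2 rose. The members fixed in advance that did not pass were HK2 (log2 fold change 0.20, adjusted p = 0.642), the hexokinase of many tumours, PFKFB3 (0.06, adjusted p = 0.899), which makes the activator of phosphofructokinase, and PKM (0.30, adjusted p = 0.245), the pyruvate kinase. The glycolysis list had a median of 0.19 and did not pass camera (adjusted p = 0.052, and adjusted p = 0.682 with an estimated correlation). It passed without control replicate 1 (adjusted p = 0.0331), ETV6 replicate 1 (adjusted p = 0.0457) or ETV6 replicate 2 (adjusted p = 0.0358).

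**Figure D1:**
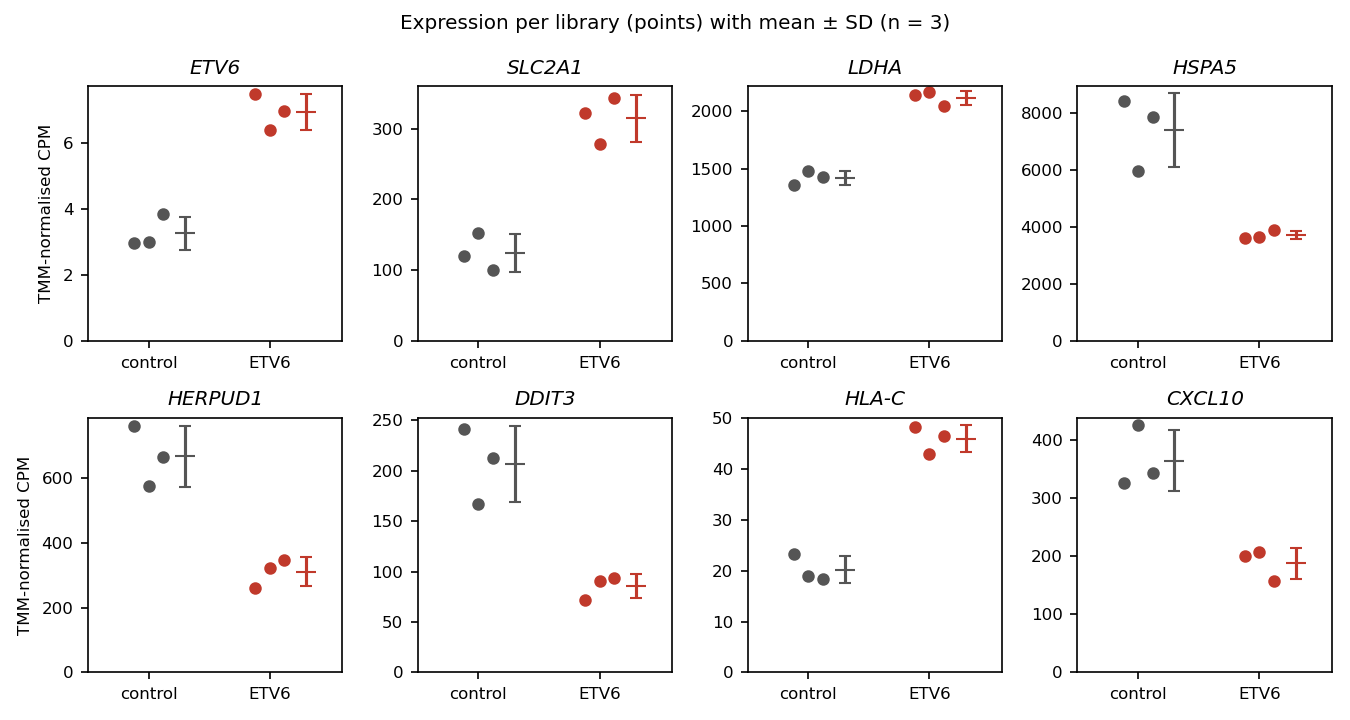
TMM-normalised CPM of 8 genes in each library, with control libraries in grey and ETV6 libraries in red; points are libraries, and the bars give the mean ± SD of the 3 libraries of a group. ETV6, SLC2A1, LDHA and HLA-C lie higher in every ETV6 library than in any control library, and HSPA5, HERPUD1, DDIT3 and CXCL10 lie lower.

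Across all tested genes, 416 changed, or 3.01%, with 224 higher and 192 lower in the ETV6 group. The largest rises among genes with a mean of at least 5 CPM were those of UCA1, a long noncoding RNA of bladder and other cancers, FRG2 and ASB2, a subunit of a ubiquitin ligase. UCA1 rose from 2.88 ± 0.055 to 11.1 ± 0.71 CPM (log2 fold change 1.94, SE 0.16, adjusted p = 5.49e-07), FRG2 by 1.89 and ASB2 by 1.70 on the log2 scale. SAA2, an acute-phase serum amyloid, rose by 1.40, followed by SLC2A1 at 1.35 and ALDH3A1, an aldehyde dehydrogenase, at 1.29. Smaller rises, between 1.14 and 1.28 on the log2 scale, were those of the chemokine gene CCL3L3, MAB21L4, the membrane protein gene DCBLD2, HLA-C, PSMB9 and IGFBP6, which binds insulin-like growth factors. The largest falls in this range were those of RAET1L, a ligand of the NKG2D receptor of natural killer cells, IL4I1, an amino acid oxidase, and DDIT3, the stress-induced transcription factor CHOP. RAET1L fell by 1.41, IL4I1 by 1.33 and DDIT3 by 1.28 on the log2 scale, which for RAET1L was a change from 8.80 ± 1.15 to 3.33 ± 0.89 CPM. IL23A, a subunit of interleukin 23, was 2.30-fold lower and DIRAS3, an imprinted gene for a small GTPase, fell by 1.17. CX3CL1, the chemokine fractalkine, fell by 1.09 and RCN3, a calcium-binding protein of the endoplasmic reticulum, fell by 0.98. The adjusted p-values of these named genes ran from 5.49e-07 for UCA1 to 0.00375 for RCN3. The call on RCN3 was lost without control replicate 2 (adjusted p = 0.0643). FRG2, SAA2 and CCL3L3 belong to families with near-identical copies, so their counts are uncertain where reads fit several copies.

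All 416 changed genes had no overlap between the libraries of the groups. As the test selects genes whose groups lie apart in these same libraries, this is no separate support. Of all tested genes, 21.6% had no overlap, against 10% expected by chance for 3 against 3. Of the changed genes, 90 moved by at least 1 on the log2 scale, 59 up and 31 down, and the smallest change called was 0.36. The count of changed genes was 167 without control replicate 1, 175 without control replicate 2, 186 without ETV6 replicate 1, 180 without ETV6 replicate 2 and 781 without ETV6 replicate 3. On the main axis of variation, which held 33.7% of the variance, ETV6 replicate 3 lay nearest to the controls. The controls stood there at -25.0, -14.4 and -19.3, and ETV6 replicates 1, 2 and 3 at 28.97, 20.1 and 9.64.

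**Figure D2:**
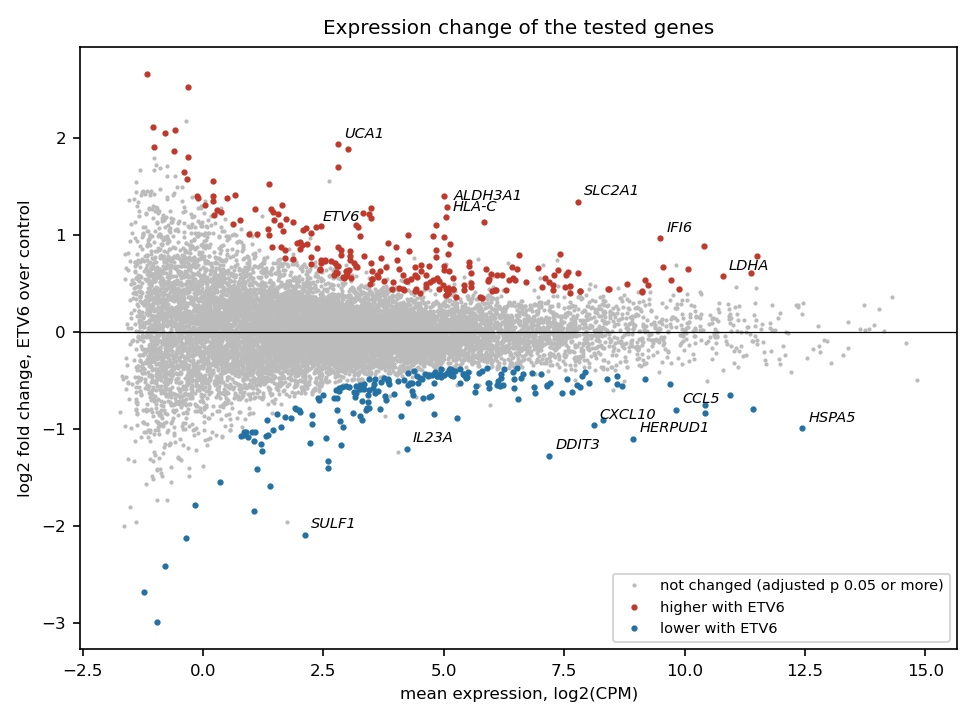
Log2 fold change of the ETV6 group over the control group (vertical axis) against mean expression as log2 CPM (horizontal axis) for the 13802 tested genes; red points are the 224 genes called higher, blue points the 192 called lower and grey points the rest. SLC2A1 and LDHA are among the abundant genes called higher, and HSPA5, HERPUD1 and DDIT3 among the abundant genes called lower.

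HSPA5, HERPUD1 and DDIT3, which respond to stress of the endoplasmic reticulum, were lower in the ETV6 group, while most genes of the 2 stress lists did not pass. HSPA5, the chaperone BiP, fell from 7414 ± 1287 to 3724 ± 141 CPM. HERPUD1, a membrane protein of endoplasmic reticulum-associated degradation, fell from 666 ± 93.6 to 311 ± 44.6 CPM, and DDIT3 from 207 ± 37.5 to 85.3 ± 11.9 CPM. In the edgeR test the log2 fold changes were -0.99 for HSPA5 (SE 0.14, adjusted p = 2.52e-04), -1.10 for HERPUD1 (SE 0.13, adjusted p = 2.41e-05) and -1.28 for DDIT3 (SE 0.13, adjusted p = 7.68e-06). HSPA5 lies on chromosome 9 from 125234853 to 125241330, HERPUD1 on chromosome 16 from 56932048 to 56944863 and DDIT3 on chromosome 12 from 57516588 to 57521737. For DDIT3, 39.6% of the annotated exonic bases are shared with other genes on either strand, so its count is less certain than those of HSPA5 and HERPUD1, which have no such overlap. Of the 20 tested genes of the unfolded protein response and its chaperones, none rose, 2 fell and 18 did not pass, and adjusted over the list alone 1 rose and 7 fell. The list as a set was lower than other genes by camera (adjusted p = 0.0471, and adjusted p = 0.469 with an estimated correlation). The camera call was lost without control replicate 2 (adjusted p = 0.0879), control replicate 3 (adjusted p = 0.0699), ETV6 replicate 2 (adjusted p = 0.0639) or ETV6 replicate 3 (adjusted p = 0.180). It was also lost with the replicate block (adjusted p = 0.0623), limma-voom (adjusted p = 0.0508) and offsets for GC content and length (adjusted p = 0.0833). Of the 31 tested genes of the integrated stress response and amino acid synthesis, DDIT3 fell, none rose and 30 did not pass, and adjusted over the list alone 2 rose and 3 fell. The count of its changed members was 7 without ETV6 replicate 3. It was 2 without control replicate 1, with no filter on low counts, with the replicate block and with the offsets for GC content and length. That list did not pass camera (adjusted p = 0.151). ATF4, its central transcription factor and chosen after its values were seen, stood at 94.8 ± 7.05 CPM in controls and 79.2 ± 9.29 CPM with ETV6 (adjusted p = 0.221).

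Some genes of antigen presentation on MHC class I were higher with ETV6. HLA-C rose from 20.2 ± 2.64 to 46.0 ± 2.66 CPM and HLA-B from 18.3 ± 1.29 to 39.2 ± 3.60 CPM, both genes for class I heavy chains. PSMB9, a catalytic subunit of the immunoproteasome, rose from 6.90 ± 1.91 to 15.6 ± 0.95 CPM, and its partner PSMB8 rose from 0.23 ± 0.13 to 1.38 ± 0.62 CPM. The log2 fold changes were 1.19 for HLA-C (adjusted p = 1.45e-06), 1.10 for HLA-B (adjusted p = 3.53e-06), 1.18 for PSMB9 (adjusted p = 1.20e-04) and 2.53 for PSMB8 (adjusted p = 0.00455). The call on PSMB8 was lost without ETV6 replicate 1 (adjusted p = 0.0588), and 20.6% of its exonic bases overlap other genes. Of the 15 tested genes of the list, 5 rose, none fell and 10 did not pass, and adjusted over the list alone 6 rose and 1 fell. The list was higher than other genes by camera (adjusted p = 8.13e-04, and adjusted p = 0.469 with an estimated correlation). HLA-C lies on chromosome 6 from 31268749 to 31272130 and HLA-B from 31269491 to 31357188, and their sequences are highly alike, so reads may be assigned to the wrong member.

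Interferon-stimulated genes moved in both directions. IFI6, an inner-membrane protein of mitochondria, rose from 487 ± 46.1 to 952 ± 29.9 CPM and IFI27 from 2133 ± 262 to 3673 ± 515 CPM. CXCL10, a chemokine for T cells, fell from 364 ± 53.1 to 188 ± 27.0 CPM, and IFITM2, a restriction factor of virus entry, from 415 ± 53.2 to 221 ± 28.5 CPM. Of the 43 tested members, 5 rose, 3 fell and 35 did not pass, and adjusted over the list alone 10 rose and 4 fell. The further members that rose were OAS1, IFITM1 and BST2, chosen after their values were seen, and the remaining fall was that of GBP2, a guanylate-binding protein, which fell by 0.92 on the log2 scale. ISG15, a ubiquitin-like modifier that was also chosen after its values were seen, stood at 18000 ± 2583 CPM in controls and 18130 ± 3127 CPM with ETV6. The list did not pass camera (adjusted p = 0.436). IFITM1 and IFITM2 are near copies, and 22.7% of the exonic bases of IFITM2 overlap IFITM1. Of the 18 tested NF-kB targets and inflammatory cytokines, none rose, 4 fell and 14 did not pass, and adjusted over the list alone 1 rose and 4 fell. The chemokine CCL5 fell from 1152 ± 203 to 661 ± 38.5 CPM, and IL32, ICAM1, an adhesion molecule, and the chemokine CCL20 fell by 0.54, 0.98 and 0.88 on the log2 scale. The call on IL32 was lost without control replicate 1 (adjusted p = 0.125), ETV6 replicate 1 (adjusted p = 0.0784) or ETV6 replicate 2 (adjusted p = 0.0853). Those on ICAM1 and CCL20 were lost without any library other than control replicate 3, with adjusted p from 0.0505 to 0.156 for ICAM1 and from 0.0618 to 0.238 for CCL20. The NF-kB list did not pass camera (adjusted p = 0.374).

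Among nuclear-encoded genes of oxidative phosphorylation and cytosolic ribosomal proteins, 2 of each list were called higher with ETV6. That is no larger a share than the 3.01% called among all tested genes. The call on each list as a set depended on the test. The camera test gave adjusted p = 0.0471 for oxidative phosphorylation and adjusted p = 0.0449 for ribosomal proteins, and both calls were lost with an estimated correlation (adjusted p = 0.682 for each). Of the 71 tested genes of oxidative phosphorylation, 2 rose, none fell and 69 did not pass, with a median of 0.12, and adjusted over the list alone none passed. NDUFB2 rose from 684 ± 104 to 994 ± 180 CPM and NDUFB8 from 130 ± 13.3 to 203 ± 56.5 CPM, both genes for accessory subunits of complex I. Of the 77 tested ribosomal proteins, RPS26 rose by 0.49 and RPL28 by 0.47 on the log2 scale, none fell and 75 did not pass, with a median of 0.16. Adjusted over the list alone, 2 ribosomal proteins rose. The count of changed ribosomal proteins was 16 without ETV6 replicate 3, 7 with no filter on low counts and 0 without any other library. Both camera calls were also lost without control replicate 2 (adjusted p = 0.391 for each), and without ETV6 replicate 1 (adjusted p = 0.471 and 0.318). With offsets for GC content and length they were lost as well (adjusted p = 0.782 and 0.548), as they were with the replicate block (adjusted p = 0.0543 for each) and with no filter on low counts (adjusted p = 0.114 for each). The single calls on NDUFB2, NDUFB8, RPS26 and RPL28 were each lost without any library other than ETV6 replicate 3, with adjusted p from 0.0527 to 0.190. For NDUFB2 and NDUFB8, 35.9% and 48.5% of the exonic bases overlap other genes. The 13 mitochondrially encoded genes had 0 counts in every library and were not tested.

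Other metabolic lists held no changed gene. Of all 13802 tested genes, 2319 had an unadjusted p under 0.05 in the edgeR test. The list counts at that level, here and below, are to be read against this share. None of the 33 tested genes of pyruvate oxidation and the TCA cycle passed the edgeR test, while 6 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom none, and adjusted over the list alone 2 fell. The members with the smallest p were MPC1, a subunit of the mitochondrial pyruvate carrier (log2 fold change -0.41, adjusted p = 0.0586), and SUCLG1, a subunit of succinyl-CoA ligase (-0.36, adjusted p = 0.0602), both chosen after their values were seen. None of the 10 tested genes of the pentose phosphate pathway passed, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. For cholesterol biosynthesis, none of 23 tested genes passed, with 2 at an unadjusted p under 0.05, and for fatty acid synthesis none of 16, with 5, and DESeq2 and limma-voom called 0 in both lists. Adjusted over the list alone, 0 genes passed in these 3 lists. The camera adjusted p-values were 0.508 for the TCA cycle, 0.867 for the pentose phosphate pathway, 0.436 for cholesterol and 0.867 for fatty acids. The pentose phosphate list had a median of 0.07, a mean of -0.02 and a camera direction of up.

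Of the 20 tested genes of the hypoxia response, 3 rose, 1 fell and 16 did not pass, and adjusted over the list alone 4 rose and 1 fell. Beside SLC2A1, BNIP3, a mitophagy receptor, rose from 49.9 ± 0.61 to 75.7 ± 10.3 CPM and ADM, the peptide hormone adrenomedullin, from 16.2 ± 2.81 to 23.6 ± 2.99 CPM. CA12, a membrane carbonic anhydrase that is also on the estrogen list, fell from 35.8 ± 3.24 to 25.9 ± 1.12 CPM. The list did not pass camera (adjusted p = 0.436), with a median of -0.01, a mean of 0.16 and a camera direction of up. The call on ADM was lost without control replicate 1 (adjusted p = 0.0909), control replicate 3 (adjusted p = 0.130), ETV6 replicate 2 (adjusted p = 0.0785) or ETV6 replicate 3 (adjusted p = 0.0567). The call on CA12 was lost without control replicate 2 (adjusted p = 0.0696), control replicate 3 (adjusted p = 0.0910), ETV6 replicate 1 (adjusted p = 0.0712) or ETV6 replicate 2 (adjusted p = 0.103).

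ELF3, an epithelial ETS factor, was the ETS-family gene that rose apart from ETV6, from 21.2 ± 1.196 to 36.2 ± 4.35 CPM (log2 fold change 0.77, SE 0.11, adjusted p = 2.76e-04). Of the 17 tested genes of the ETS list, which leaves out ETV6, 1 rose, none fell and 16 did not pass, and the count adjusted over the list alone was the same. MYC, the proliferation-linked transcription factor, rose from 16.4 ± 0.67 to 26.1 ± 0.84 CPM (log2 fold change 0.67, SE 0.11, adjusted p = 9.41e-04). MYC was the single member to change among the 21 tested FBXW7 substrates and the 18 tested immediate early genes, with 20 and 17 not passing. Adjusted over the list alone, 1 rose in each. Among the 16 tested targets of MAPK feedback and ERK, MYC rose, 3 fell and 12 did not pass, and adjusted over the list alone 1 rose and 5 fell. The falls were those of SPRY4 and SPRY2, feedback inhibitors of receptor tyrosine kinase signalling, and PHLDA1, by 0.60, 0.62 and 0.86 on the log2 scale. These 3 falls were each lost on leaving out at least 4 of the 6 libraries in turn, and the highest adjusted p was 0.145 for SPRY4, 0.247 for SPRY2 and 0.137 for PHLDA1. The call on SPRY2 was lost in 13 of the 17 alternatives run on it, RLE, total-count and upper quartile scaling among them. None of these 4 lists passed camera, with adjusted p = 0.643 for ETS factors, 0.867 for FBXW7 substrates, 0.796 for immediate early genes and 0.436 for the MAPK list.

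Of the 16 tested angiogenic and secreted growth factors, 2 rose, none fell and 14 did not pass, and adjusted over the list alone 2 rose and 1 fell. IGFBP6 rose from 35.6 ± 8.76 to 78.2 ± 5.96 CPM and FGF19, an endocrine fibroblast growth factor, from 24.2 ± 3.83 to 45.6 ± 6.86 CPM, while the list did not pass camera (adjusted p = 0.867, median -0.02, mean 0.09, camera direction up). Of the 10 tested TGF-beta and BMP targets, ID1, an inhibitor of differentiation factors, rose by 0.38, TGFBI, an extracellular matrix protein, fell by 0.67 and 8 did not pass. Adjusted over the list alone, 1 rose and 2 fell. The call on ID1 was lost without any library other than ETV6 replicate 3 (adjusted p from 0.102 to 0.219), and that on TGFBI without control replicate 2 (adjusted p = 0.0613) or ETV6 replicate 2 (adjusted p = 0.0597). None of the 10 tested Notch targets or the 9 tested Wnt targets passed the edgeR test, with 1 and 0 at an unadjusted p under 0.05, and DESeq2, limma-voom and the adjustment over the list alone also gave 0. Camera gave adjusted p = 0.797 for TGF-beta and BMP, 0.436 for Notch and 0.486 for Wnt, where the median was 0.03, the mean -0.14 and the direction down.

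Of the 13 tested estrogen response genes, 2 rose, 1 fell and 10 did not pass, and adjusted over the list alone 2 rose and 6 fell. TFF3, a secreted trefoil peptide, rose from 96.7 ± 8.05 to 153 ± 2.30 CPM and AGR2, a secretory disulfide isomerase, from 66.4 ± 7.63 to 96.6 ± 4.92 CPM. The call on AGR2 was lost without control replicate 1 (adjusted p = 0.0596) or ETV6 replicate 2 (adjusted p = 0.0527). Of the 25 tested epithelial identity genes, RAB25, a GTPase of epithelial recycling endosomes, fell from 23.9 ± 0.58 to 16.7 ± 0.67 CPM, none rose and 24 did not pass. That call was lost without control replicate 1 (adjusted p = 0.0515), and adjusted over the list alone 1 fell. Of the 16 tested genes of epithelial-mesenchymal transition, TGFBI and ZEB1, a repressor of epithelial genes, fell, none rose and 14 did not pass, and adjusted over the list alone 2 fell. ZEB1 stood at 2.41 ± 0.31 and 1.18 ± 0.25 CPM, and its call was lost on leaving out any of the 6 libraries (adjusted p from 0.0540 to 0.186). Of the 24 tested p53 targets, GDF15, a stress-induced cytokine, fell by 0.42, none rose and 23 did not pass, and adjusted over the list alone 2 fell. Of the 21 tested genes of autophagy and lysosomes, CTSB, a lysosomal protease, rose by 0.42, none fell and 20 did not pass, and adjusted over the list alone 1 rose. The call on GDF15 was lost without control replicate 1, control replicate 2, ETV6 replicate 1 or ETV6 replicate 2 (adjusted p from 0.102 to 0.278), and that on CTSB without any library other than ETV6 replicate 3 (adjusted p from 0.0527 to 0.199). None of the 39 tested cell cycle genes passed the edgeR test, adjusted over the list alone included, with 5 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. None of these 6 lists passed camera, with adjusted p = 0.436 for estrogen response, epithelial identity, epithelial-mesenchymal transition and p53 targets, and 0.764 for lysosomes and the cell cycle.

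Markers of other cells and of RNA quality were measured beside these groups. Replication-dependent histone transcripts, which mostly lack a polyA tail, were higher as a set with ETV6 (camera adjusted p = 8.13e-04, and adjusted p = 0.379 with an estimated correlation). Of 13 tested histone genes, none passed singly, with 5 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, while adjusted over the list alone 4 rose, and the median was 0.50. This list moved in the same direction as antigen presentation, oxidative phosphorylation and ribosomal proteins, and opposite to the unfolded protein response. Of 7 tested nuclear and non-polyadenylated RNAs, KCNQ1OT1, an imprinted antisense RNA, fell by 0.60, none rose and 6 did not pass, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.524). The call on KCNQ1OT1 was lost without any library other than ETV6 replicate 3 (adjusted p from 0.0581 to 0.245). Of 6 tested markers of neural-type kidney lines such as HEK293, NEFH, a neurofilament, rose from 1.78 ± 0.38 to 4.45 ± 0.37 CPM and GAL, the neuropeptide galanin, from 6.44 ± 1.91 to 12.8 ± 3.74 CPM, while 4 did not pass. Adjusted over the list alone 2 rose, and the list did not pass camera (adjusted p = 0.052), except without control replicate 3 (adjusted p = 0.00555). The call on GAL was lost without control replicate 1, control replicate 2, ETV6 replicate 1 or ETV6 replicate 2 (adjusted p from 0.0672 to 0.153) as well as with offsets for GC content and length (adjusted p = 0.0846), the replicate block (adjusted p = 0.133) and glmTreat. Among 2 tested fibroblast, 4 endothelial, 2 haematopoietic and 7 ciliated-cell markers, none passed the edgeR test, with 0, 1, 0 and 1 at an unadjusted p under 0.05. DESeq2 called 1 ciliated-cell marker and limma-voom 0, and adjusted over the list alone 1 ciliated-cell marker rose. Camera gave adjusted p = 0.436 for endothelial and 0.486 for ciliated-cell markers, and the fibroblast and haematopoietic lists were too short for it.

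**Figure D3:**
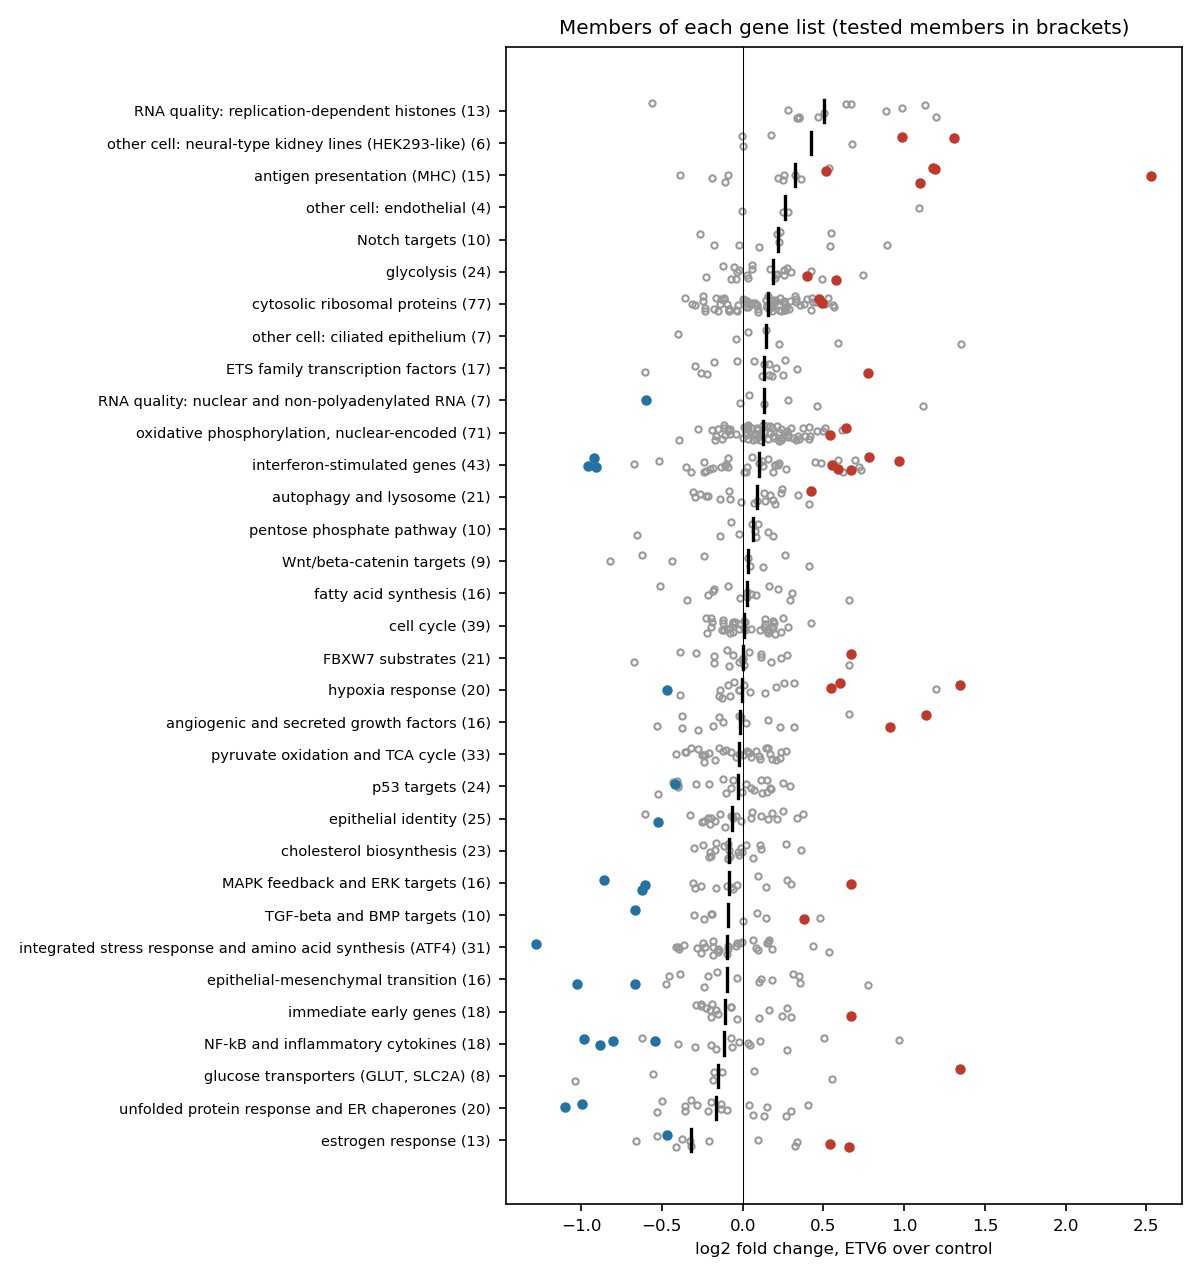
Log2 fold change of the ETV6 group over the control group (horizontal axis) for the members of each gene list with 3 or more tested members; each point is a gene, red if called higher, blue if called lower and open grey otherwise, the black bar is the list's median, and the number in brackets counts the tested members. The histone list has the highest median, at 0.50, and the estrogen response list the lowest, at -0.32.

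The fry test, which asks whether the members of a list move on balance in 1 direction, gave adjusted p = 0.0203 for antigen presentation (up), for the unfolded protein response (down) and for the histone list (up). For oxidative phosphorylation fry gave adjusted p = 0.443 and for ribosomal proteins adjusted p = 0.399, and none of the other lists fixed in advance had a fry adjusted p under 0.175. No list kept its camera call with an estimated correlation between its genes. For the histone and unfolded protein response lists that estimate was -0.0038 and -0.028, below the preset 0.01. Correlated genes thus do not account for the loss of these calls, where the unadjusted camera p was 0.0115 and 0.0426. The estimate was 0.048 for antigen presentation, against 0.273 for oxidative phosphorylation and 0.237 for ribosomal proteins. As camera with an estimated correlation also has fewer degrees of freedom, a call lost there is not by itself a sign of correlated genes.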

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

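The offsets for GC content and length were chosen after seeing the data, and the other alternatives before. The rise of ETV6, that of SLC2A1 and the count of 1 changed glucose transporter held under every alternative run, and no called gene changed sign in any of them. The number of changed genes, 416, was between 338 and 586 with other scalings, filters and tools, with the replicate block and with the offsets. The replicate block gave 338, of which 315 were among the 416, and its number check found correlations of -0.06, 0.06 and -0.04 between same-numbered libraries. With an adjusted p under 0.01 it was 161, with an absolute log2 fold change of at least 1 it was 90, and with glmTreat it was 120 (73 higher, 47 lower), as stricter thresholds must lower it. With the offsets for GC content and length 586 genes changed, 262 higher and 324 lower, so that the share of rises was 44.7% against 53.9%; the cause was not tested. With upper quartile and total-count scaling that share was 59.7% and 58.3%.

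Leaving out a library moved the counts further. Without control replicates 1, 2 and 3 the numbers higher were 97, 87 and 158 and the numbers lower 70, 88 and 123. Without ETV6 replicates 1, 2 and 3 they were 107, 108 and 427 higher and 79, 72 and 354 lower, and the totals were 167, 175, 281, 186, 180 and 781. The larger count without ETV6 replicate 3 arose despite fewer libraries; the cause was not tested.

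The glycolysis list had 2 changed members, LDHA and PFKP, and 1, LDHA, with total-count scaling. With no filter on low counts, limma-voom, the fit without the robust option and the replicate block the count was again 2, but LDHB was called in place of PFKP. In these settings LDHB, another lactate dehydrogenase subunit, rose by 0.69 to 0.75 on the log2 scale, more than LDHA at 0.56 to 0.58. The list had 0 changed members without control replicate 1 or ETV6 replicate 2, 1 without control replicate 2, control replicate 3 or ETV6 replicate 1, and 3 without ETV6 replicate 3, LDHB being the added gene. The mean log2 fold change of the list was 0.17 (adjusted p = 0.052) and lay between 0.106 and 0.208 over all alternatives, with adjusted p from 0.0267 to 0.682. It passed with a filter of at least 1 CPM in 3 libraries (0.175, adjusted p = 0.0395), with the offsets (0.170, adjusted p = 0.0267) and without control replicate 1 (0.208, adjusted p = 0.0331), ETV6 replicate 1 (0.179, adjusted p = 0.0457) or ETV6 replicate 2 (0.196, adjusted p = 0.0358); the cause was not tested. The calls on PFKP, SPRY2, GDF15, ID1 and KCNQ1OT1 were lost with at least total-count scaling, and those on CCL20, CTSB, GAL, NDUFB2, RPL28 and ZEB1 with at least 1 other setting apart from glmTreat and left-out libraries. Among 60 called genes that the rule names, DESeq2 lost 0, limma-voom 8, the fit without the robust option 10 and glmTreat 24.

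On simulated data 52.5% of genes changed 1.5-fold and 86.3% of genes changed 2-fold were recovered, and all 40 genes changed 4-fold. Changes under 1.5-fold, and changes of genes with a mean of 1 CPM or less, were not simulated.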

Other observations

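SULF1, MUC5AC and the genes named with them were chosen after their values were seen. SULF1, which removes sulfate groups from heparan sulfate, fell from 7.01 ± 1.32 to 1.64 ± 0.50 CPM (log2 fold change -2.09, adjusted p = 7.68e-06). Other single genes that fell were the small GTPase gene ARF4, from 2415 ± 281 to 1535 ± 51.7 CPM (adjusted p = 0.00477), the golgin gene GOLGA3 by 0.62, and GBF1, an activator of ARF proteins, by 0.44 on the log2 scale. CCL22, a chemokine for regulatory T cells, fell by 1.59 (adjusted p = 3.68e-04) and IFNB1, which encodes interferon beta, by 0.54 (adjusted p = 0.042).

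Among single genes, MUC5AC, a gel-forming mucin, rose from 18.4 ± 2.67 to 36.5 ± 4.94 CPM (adjusted p = 5.65e-05), and CST6, a protease inhibitor of squamous epithelia, from 21.8 ± 0.83 to 42.8 ± 5.80 CPM (adjusted p = 2.13e-05). MET, the receptor of hepatocyte growth factor, rose from 5.94 ± 0.61 to 12.6 ± 0.65 CPM (adjusted p = 9.71e-05), and LAMA3, a laminin subunit, by 0.65 on the log2 scale. SAA1 rose from 945 ± 81.1 to 1747 ± 377 CPM (adjusted p = 8.95e-04), though reads that fit SAA1 and SAA2 alike make the split between them uncertain.

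Of the tests that follow, those on oxygen shortage, on a lower unfolded protein response and on interferon were chosen only after the result was seen, and the 5 added lists and the offsets after the single genes were seen. Bootstrap intervals of a median resampled the genes of a list, so they give the spread between genes and not between libraries. SLC2A1 and LDHA rose with ETV6. GC content or length bias is argued against by the offsets, with which the larger adjusted p of both genes was 0.00432 and the log2 fold changes were 1.37 and 0.54. Oxygen shortage in the ETV6 dishes stays open: the other 19 tested hypoxia genes went both ways, with a median log2 fold change of -0.0228 (95% bootstrap interval -0.0881 to 0.207), and BNIP3 and ADM rose while CA12 fell. By the earlier rule this median and interval would have counted against oxygen shortage. Higher MYC activity stays open too, as the median of 30 tested ribosome biogenesis genes was 0.0918 (0.0128 to 0.155), with fry adjusted p = 0.0106 (up), camera adjusted p = 0.135 at the preset correlation and adjusted p = 0.206 with an estimated correlation. An effect of ETV6 on the 2 genes may be direct or indirect, which counts cannot tell apart. Whether infection, the vector or the state of the control cultures lies behind the 2 rises in place of ETV6 stays open too.

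HSPA5, HERPUD1 and DDIT3 fell with ETV6. Scaling is argued against by the largest adjusted p of these genes over RLE, total-count and upper quartile scaling, 3.05e-04, and GC content or length bias by the largest adjusted p with the offsets, 6.61e-05. The other 18 tested genes of the unfolded protein response had a median of -0.13 (-0.284 to 0.0837), with 11 lower, and the unadjusted p-value of the fry test of limma was 0.0415. That interval gives the spread between these genes, whereas fry rests on the libraries. As the interval includes 0, a lower unfolded protein response stays open by the stricter rule, although the fry p-value and the negative median met the earlier rule. Whether ETV6, the vector or the state of the control cultures lies behind the 3 falls stays open too, as the controls may have been under more stress.

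HLA-B, HLA-C, PSMB8 and PSMB9 rose with ETV6. Blood cells in the ETV6 cultures stay open: the summed haematopoietic markers were higher by 0.750 CPM (1.87 ± 0.41 and 2.62 ± 0.62 CPM), a difference close to the spread between libraries. By the earlier rule a difference of this size would have counted against blood cells. CD3E, CD2, MS4A1, CD68, CD163 and NKG7 had 0 counts in every library, which goes against such cells only if these genes were counted. Stronger interferon signalling stays open, since the interferon-stimulated genes had a median of 0.101 (-0.0929 to 0.201) and the unadjusted p-value of the fry test of limma was 0.0912, while CXCL10 and IFNB1 fell. How far reads shared between HLA-B and HLA-C enter their counts also stays open. If the controls were not infected, an effect of infection or of the vector on these genes cannot be told apart from one of ETV6.

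The added lists left out the genes already seen to change. The early secretory pathway had a median of -0.180 (-0.248 to -0.124) over 45 tested genes, 40 of them lower. Camera called it lower at the preset correlation (adjusted p = 6.62e-06) and not with an estimated correlation (adjusted p = 0.114, unadjusted 0.0228), while fry gave adjusted p = 0.0106 (down). The members thus fell on balance by fry, and whether they fell more than other genes stays open. By the earlier rule, which used unadjusted camera p-values, the list would have counted as lower. At the preset correlation and with the offsets for GC content and length, the unadjusted camera p was 2.41e-06 and the mean went from -0.1851 to -0.1945. None of the 45 was called by edgeR, which carries no weight because genes seen to be called were left out of the list. An unadjusted p under 0.05 was found for 17, DESeq2 called 1 and limma-voom 0, and 6 fell when adjusted over the list alone. NRF2 targets had a median of 0.177 (0.0755 to 0.211) and mitochondrial ribosomal proteins one of 0.121 (0.0254 to 0.189). Both passed camera at the preset correlation (adjusted p = 0.0451 and adjusted p = 0.0199) and not with an estimated correlation (adjusted p = 0.184 and adjusted p = 0.206), and fry gave adjusted p = 0.0402 and adjusted p = 0.0508 (both up). With the offsets for GC content and length the unadjusted camera p-values were 0.0852 and 0.708. The mean of the NRF2 targets went from 0.17 to 0.15 and that of the mitochondrial ribosomal proteins from 0.12 to 0.07, so both lists stay open. The list of mucin and squamous genes did not pass camera (adjusted p = 0.603) or fry (adjusted p = 0.692), with a median of -0.0639 (-0.187 to 0.470), a mean of 0.18 and 10 of 19 tested genes lower, and whether they rose together stays open. By the earlier rule the negative median would have counted against a joint rise.

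The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 416 genes, 1 of 10 splits reached that number, and the highest other split called 2.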
